A study of Hormonema carpetanum with 4 samples.

How the data were processed

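Total RNA was taken from mycelium in fermentation broth and made into sequencing libraries with a SMARTER mRNA-Seq kit, per the labels' protocols. The deposited table holds TPM values for 4 libraries and 10951 genes, rounded by the authors to 2 decimals. Each column sums to 1000000 within rounding, which was checked on the values. TPM divides a gene's reads by its length and by the library's total, so a few very high genes lower the values of all others, and the read depth is lost. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here, nor are gene lengths or coordinates, so genes are identified by the table's gene numbers. The table pairs gene numbers with best database hits. Of its genes, 1744 have a symbol, 6704 a Swiss-Prot hit, 9695 an Nr hit and 4170 a KEGG orthology number. A name given here is that of the best hit, taken from Swiss-Prot, then Nr, then KEGG, and does not show that the function is the same.

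Columns were matched to samples by the library names in the labels. Groups came from the sample titles, with 1 library in each of the 4 groups. The titles give day 14 for the wild type and for 1 mutant library, and day 18 with 19 °C or 25 °C for the others, while the extraction protocol states 18 days for both strains; the titles were followed. No temperature is given for the day 14 libraries. Which strain differences come from the mutations and which from the cultures cannot be separated with 1 culture per group.

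Ratios were computed as the difference of log2 of TPM plus a pseudocount of 1. A gene entered a comparison when it reached 1 TPM in at least 1 of the 2 libraries, and was called higher or lower at a 2-fold ratio. Folds printed beside TPM values are plain ratios of TPM. No count model was run, since TPM are not counts, and no p-value across genes was computed with 1 library per group. Bootstrap intervals over genes, 1000 random gene orders and exact intervals on shares of genes and on list medians describe these libraries and are no test of the conditions. Of the table's genes, 779 are at 0 in all 4 libraries. Exact zeros are reported as listed, without a fold. Values identical to those of another gene in every library, to 2 decimals, were found for 166 genes in 68 sets, 16 of them at 10 TPM or more. Whether they are near-identical copies or ties of rounded low values was not checked. None of the genes named in the report is among them.

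Gene lists were fixed before the data were examined, as 38 lists of patterns in gene names or orthology numbers. A list with at least 5 tested members was described by its median and by the percentile of that median among 10000 random lists of the same size, drawn with replacement within 20 bins of mean expression. The percentile describes these libraries and is no test of the conditions. Several lists caught wrong members, which were kept as fixed. The list meant for mitochondrially encoded genes matched 0 genes and the fatty acid desaturation list 4, with 1 higher and 1 lower in the mutant. The list meant for ribosomal RNA held 9 genes for enzymes that act on ribosomal RNA, so it says nothing of RNA quality; its percentile was 69.0 in the strain comparison. The list meant for other organisms matched 304 genes through the source organism of the best hit, so it measures no contamination; its percentiles were 66.1 for strain and 99.7 for temperature. Of the 112 cytosolic ribosomal protein genes, 38 are named as mitochondrial.

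Named genes followed a rule fixed before the data were examined. For each of the strain and temperature comparisons it takes the 10 largest and 10 smallest ratios among named genes at 10 TPM or more in either library, the extreme members of each list, and the members of the mevalonate, ergosterol and triterpene lists at 10 TPM or more. For the comparisons over time it takes 3 in each direction. The stretch of 16 gene numbers around efuA, the lists of long and short proteins, the day 14 comparison of efuA, and the examples efuB, the efu hits elsewhere, 3-isopropylmalate dehydrogenase, citrate synthase, phosphoglycerate kinase, mcm7, histones H2B and H3, histone H4.1 between the strains, acyl-CoA oxidase, the large chain of ribonucleotide reductase, sec11, nucleolar GTP-binding protein 2 and the 30 kDa heat shock protein between temperatures were chosen after values were seen.

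Alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter, a filter of 10 TPM, a 4-fold threshold, rescaling by the median ratio over genes at 1 TPM or more in all 4 libraries, rescaling to 1000000 without the 20 highest genes, and random lists not matched on expression. Counts without genes listed at 0, and the ribosomal list without mitochondrial names, were added after seeing the data. The steps were tested on simulated data made from the mutant day 14 column, with 200 of 8974 tested genes changed and noise of SD 0.3 on the log2 scale. All 67 genes changed 4-fold and all 66 changed 8-fold were called in the right direction, as were 44.8% of the 67 changed 2-fold, at the threshold itself, and 2 of 8774 unchanged genes were called. Of 100 unshifted random lists of 30 genes, 96 lay between the percentile bounds, and all 100 lists shifted by 0.5 lay above the upper bound. The simulated noise held no counting error and no length trend. The strain ratios in the data spread wider, with quartiles of -0.35 and 1.64. The simulated rates therefore do not say how often calls in the data are right. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.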

Results

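Gene expression was measured by RNA-seq in mycelium of Hormonema carpetanum, a filamentous fungus that makes enfumafungin, a triterpene glycoside that inhibits the fungal cell wall enzyme beta-glucan synthase. The study set out to raise enfumafungin production by mutagenesis and by changing the fermentation. Its libraries came from the wild-type strain ATCC 74360 at day 14, the mutant ENF-5-29 at day 14, and the same mutant at day 18 at 19 °C and at 25 °C. Each of the 4 groups had 1 library, so no difference reported here has a replicate check, and no p-value is given. The sample titles gave day 14 for the first pair of libraries without a temperature, whereas the extraction protocol named 18 days of fermentation for both strains. Values were TPM, transcript abundances scaled to a library total of 1000000, for 10951 genes, and this unit keeps no read depth, so the counting error of a value is unknown. The libraries held between 8569 and 8942 genes at 1 TPM or more. The 20 highest genes took 23.5% of the TPM of the wild-type library and between 14.1% and 16.1% of that of the mutant libraries. Across 9508 genes the Spearman correlation of the wild-type library with the mutant libraries lay between 0.672 and 0.741, and that among the mutant libraries between 0.863 and 0.907. These correlations are across genes, which are not independent replicates.

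The mutant was first compared with the wild type at day 14, the comparison that addresses what differs between the strains. Of the 13 gene models of the enfumafungin cluster, 11 were higher in the mutant library, by 2.54-fold to 89.4-fold, and 2 lay within 2-fold on the log2 scale of TPM plus 1. In these deposited values all tested genes had a median log2 ratio of 0.64, which rescaling by the median ratio moved by -0.70. The calls for efuL, efuF and efuE, with log2 ratios of 1.61, 1.45 and 1.17, therefore depended on the scaling. So did that for an efuK model (gene04129), at -0.95. Enfumafungin synthase efuA (gene04134), the terpene cyclase that gives the pathway its carbon skeleton, stood at 31.65 TPM in the wild type and 2829 TPM in the mutant, an 89.4-fold difference. The cytochrome P450 genes efuG (gene04133) and efuH (gene04132) were 87.5-fold and 67.3-fold higher, and the hydroxylase or desaturase gene efuI (gene04131) was 77.3-fold higher and reached 15829 TPM. Outside the cluster, genes of glycolysis, the citrate cycle, fatty acid oxidation and DNA replication were higher in the mutant as groups. The lists of sugar and other facilitator transporters and of carbohydrate-active secreted enzymes had medians low among all genes, though their members went both ways.

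Of 21 gene models with a best Swiss-Prot hit to an efu protein, 13, for 12 proteins, lay in a stretch of 16 consecutive gene numbers and 8 elsewhere. The summed TPM of those in the stretch was 537.7 in the wild type and 30127 in the mutant at day 14. The acetyltransferase gene efuC (gene04141) was 40.0-fold higher, at 46 TPM, and the gene annotated as a self-resistance protein, efuJ (gene04130), was 12.9-fold higher, at 921.4 TPM. The transcription factor gene efuD (gene04140) was 4.29-fold higher and the reductase gene efuL (gene04127) 3.10-fold higher, and the transporter gene efuF (gene04137) and the dehydrogenase gene efuE (gene04138) were 4.66-fold and 2.54-fold higher. A pair of gene models matched the transporter efuK, of which gene04128 was 4.14-fold higher and gene04129 had 16.6 TPM in the wild type and 8.13 TPM in the mutant. The P450 gene efuB (gene04142) stood at 1.56 and 1.69 TPM. Of the 8 models elsewhere, 3 were higher in the mutant, 3 lower, 1 within 2-fold and 1 listed at 0 in every library. Among these an efuB hit (gene05027) was 17.2-fold higher, at 27.1 and 466.0 TPM, whereas an efuI hit (gene06638) stood at 428.8 and 56.6 TPM and an efuE hit (gene08787) at 30.6 and 5.83 TPM. For efuA, efuG, efuH and efuC the lowest of the 3 mutant libraries was still 28.04, 32.7, 19.9 and 26.7 times the wild-type value. For efuI it was 10.1 times and for efuD 2.90 times, but for efuF, efuL, efuK (gene04128), efuJ and efuE it was 1.87, 1.82, 1.53, 1.26 and 1.002 times.

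**Figure D1:**
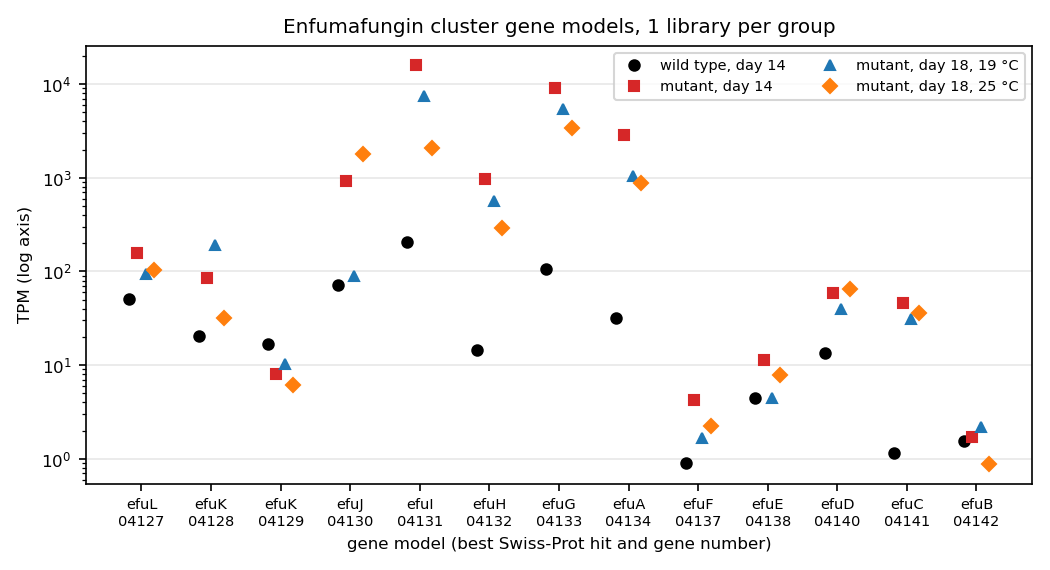
TPM on a log axis for the 13 gene models with efu best hits, in gene-number order, with 1 point per library. The wild-type points of efuA, efuG, efuH and efuC lie below all 3 mutant points, and the 19 °C and 25 °C points of efuJ lie at 90.1 and 1787 TPM.

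Of the 11 tested members of the mevalonate list, whose enzymes supply isoprenoid units, 5 were at least 2-fold higher in the mutant and 0 were lower, and the list's median log2 ratio was 0.98, at the 79.3 percentile of random lists. The largest ratios were those of a second copy of hydroxymethylglutaryl-CoA reductase (gene06242), at 0.76 TPM in the wild type and 11.01 TPM in the mutant, and of diphosphomevalonate decarboxylase ERG19 (gene04718), at 2.09 and 12.7 TPM. Hydroxymethylglutaryl-CoA synthase (gene01440) stood at 168.4 TPM in the wild type and 542.8 TPM in the mutant, and phosphomevalonate kinase ERG8 (gene06988) at 121.9 and 340.0 TPM. The main copy of the reductase (gene03104), often the rate-limiting step, stood at 35.9 and 67.3 TPM. One member of this list, an endoplasmic reticulum remodelling protein (gene09132), is no enzyme of the pathway. In the ergosterol list, 7 of 18 members were higher and 1 was lower, with a median at the 57.7 percentile. The largest ratios were those of 3-keto-steroid reductase erg27 (gene09087), at 7.25 and 45.01 TPM, and of a P450 gene with a best hit to oblE (gene02026), at 110.7 and 553.8 TPM. Squalene epoxidase erg1 (gene02835), which makes the precursor of sterols, stood at 66.7 TPM in the wild type and 140.8 TPM in the mutant, and squalene synthase erg9 (gene09579) at 86.1 and 79.1 TPM. The lower member was a gene with the symbol ERG3 (gene05078), the sterol C-5 desaturase, at 4956 and 1278 TPM.

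In the whole table, 3772 of 9272 tested genes were at least 2-fold higher in the mutant and 1301 were at least 2-fold lower. The median log2 ratio of all tested genes was 0.64, so the values below are also given relative to that shift. Higher genes made up 74.4% of these calls in the deposited values and 72.2% after rescaling without the 20 highest genes. Rescaling by the median ratio, which by construction brings the median near 0, gave 48.9%, with 2281 higher and 2385 lower genes. Ratios are log2 of TPM plus 1, which understates differences of low genes.

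Of 36 fixed lists with at least 5 tested members, 7 had a median in the highest 2.5% of random lists matched on expression and 3 in the lowest 2.5%. Glycolysis had the highest median relative to all genes, 1.27 above it on the log2 scale, with 13 of 20 members higher and 3 lower. Among its members, phosphoglycerate kinase (gene00555) stood at 66.5 TPM in the wild type and 663.7 TPM in the mutant, a phosphoglycerate mutase-like gene (gene09416) at 1.36 and 91.1 TPM, and a hexokinase (gene01952) at 153.6 and 31.6 TPM. In the citrate cycle list 19 of 30 members were higher and 1, the glyoxylate bypass enzyme isocitrate lyase (gene08880), was lower, and the median lay 0.83 above that of all genes. Its largest ratios belonged to the lysine synthesis enzyme homocitrate synthase (gene06190), at 9.77 and 328.5 TPM, and to 3-isopropylmalate dehydrogenase (gene06698) of leucine synthesis, which the list's pattern also matched, whereas citrate synthase itself (gene07675) had a log2 ratio of -0.42. In the list for fatty acid oxidation and peroxisomes 28 of 46 members were higher and 3 lower. There, an acyl-CoA dehydrogenase gene (gene09334) stood at 19.98 and 628.5 TPM, and a peroxisomal acyl-CoA oxidase gene (gene04648), which starts peroxisomal chain shortening, at 13.4 and 121.9 TPM. The histone and DNA replication list had 35 of 55 members higher and 5 lower, with the replicative helicase gene mcm7 (gene04329) at 2.89 and 36.5 TPM and histone H2B (gene05347) at 352.1 and 2251 TPM, whereas the more abundant histone H4.1 (gene01010) stood at 3521 and 1578 TPM. Of 58 heat shock and chaperone genes, 30 were higher and 5 lower, and their percentile of 98.8 became 95.1 with random lists not matched on expression. The histone chaperone asf1 (gene00222) stood at 3.98 and 101.4 TPM, whereas a 30 kDa heat shock protein gene (gene01826) stood at 3724 and 139.9 TPM. In the cytochrome P450 list 34 of 61 were higher and 6 lower, cluster genes included, and in the triterpene list, which also holds the cluster, 17 of 27 were higher and 3 lower. In this pair of libraries the 33 genes of proteins known to be very long had a median log2 ratio of 1.16, with 19 higher and 1 lower, and the 55 genes of proteins known to be very short had a median of 0.08, with 16 higher and 9 lower.

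The lists with a median in the lowest 2.5% were sugar and other major facilitator transporters, carbohydrate-active secreted enzymes, and secreted proteases and lipases. Their medians lay at -0.49, -0.53 and -0.54 relative to all genes. Their own medians were 0.16, 0.11 and 0.11 in the deposited values and below 0 after rescaling by the median ratio, so their direction depended on the scaling. Of 173 tested facilitator transporters, 55 were higher in the mutant and 32 lower. The transporter paaT (gene09898) stood at 2835 TPM in the wild type and 3.88 TPM in the mutant, and the sugar transporter STL1 (gene08949) at 3.04 and 205.7 TPM. Polygalacturonase (gene08871), which cuts pectin, stood at 8803 and 43.0 TPM, and pectinesterase (gene00372), which removes its methyl groups, at 482.8 and 1.52 TPM. Of 92 tested carbohydrate-active genes, 22 were higher and 26 lower, with the cutinase gene gene05570 higher, at 2.96 and 221.4 TPM. Cyanide hydratase (gene06460) stood at 684.6 and 4.78 TPM, a catalase (gene00218) at 338.7 and 2.64 TPM, the efflux pump FUB11 (gene09553) at 170.1 and 0.96 TPM, and the cell wall glucanosyltransferase gel2 (gene02124) at 173.2 and 2.68 TPM. In the same direction were the alcS gene (gene08084), an NADH dehydrogenase gene (gene05840) and a lysophospholipase gene (gene02609), with log2 ratios of -6.39, -6.28 and -5.39.

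Among named genes outside the cluster, alcohol oxidase 1 (gene00568) had the largest log2 ratio in favour of the mutant, 7.85, at 7.01 and 1845 TPM. A gene with a pretoxin domain (gene10410) followed at 8.22 and 1892 TPM, then a beta-lactamase-like gene of the sdnR type (gene00365) at 0.58 and 267.9 TPM, a short-chain dehydrogenase gene (gene02698) at 0.80 and 215.3 TPM, and the spore wall gene DIT1 (gene05643) at 0.35 and 154.9 TPM. A RutC family gene (gene10399), a tartrate dehydrogenase gene (gene06426) and a hetero-Diels-Alderase gene (gene10154) were listed at 0 in the wild type and at 121.1, 79.5 and 76.2 TPM in the mutant. Exact zeros in this table also fall on the signal peptidase gene sec11 (gene08643), which cells need to grow, so no absence is read from them. Melanin genes were split. The scytalone dehydratase gene (gene06769) stood at 71.0 and 1291 TPM, but a tyrosinase gene (gene08042) stood at 259.8 and 9.97 TPM. The list as a whole had 9 of 19 members higher and 3 lower, at the 64.8 percentile. In the list of polyketide and nonribosomal peptide synthases 2 of 13 were higher and 3 lower, at the 8.45 percentile, with PKS1 (gene01398) at 1.54 and 82.6 TPM and apvA (gene07248) at 19.5 and 0.37 TPM. Mitochondrial superoxide dismutase (gene10272) stood at 87.0 and 4608 TPM. The sporulation and surface list, a marker set for other cell forms, had 7 of 18 members higher and 2 lower, at the 47.3 percentile.

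**Figure D2:**
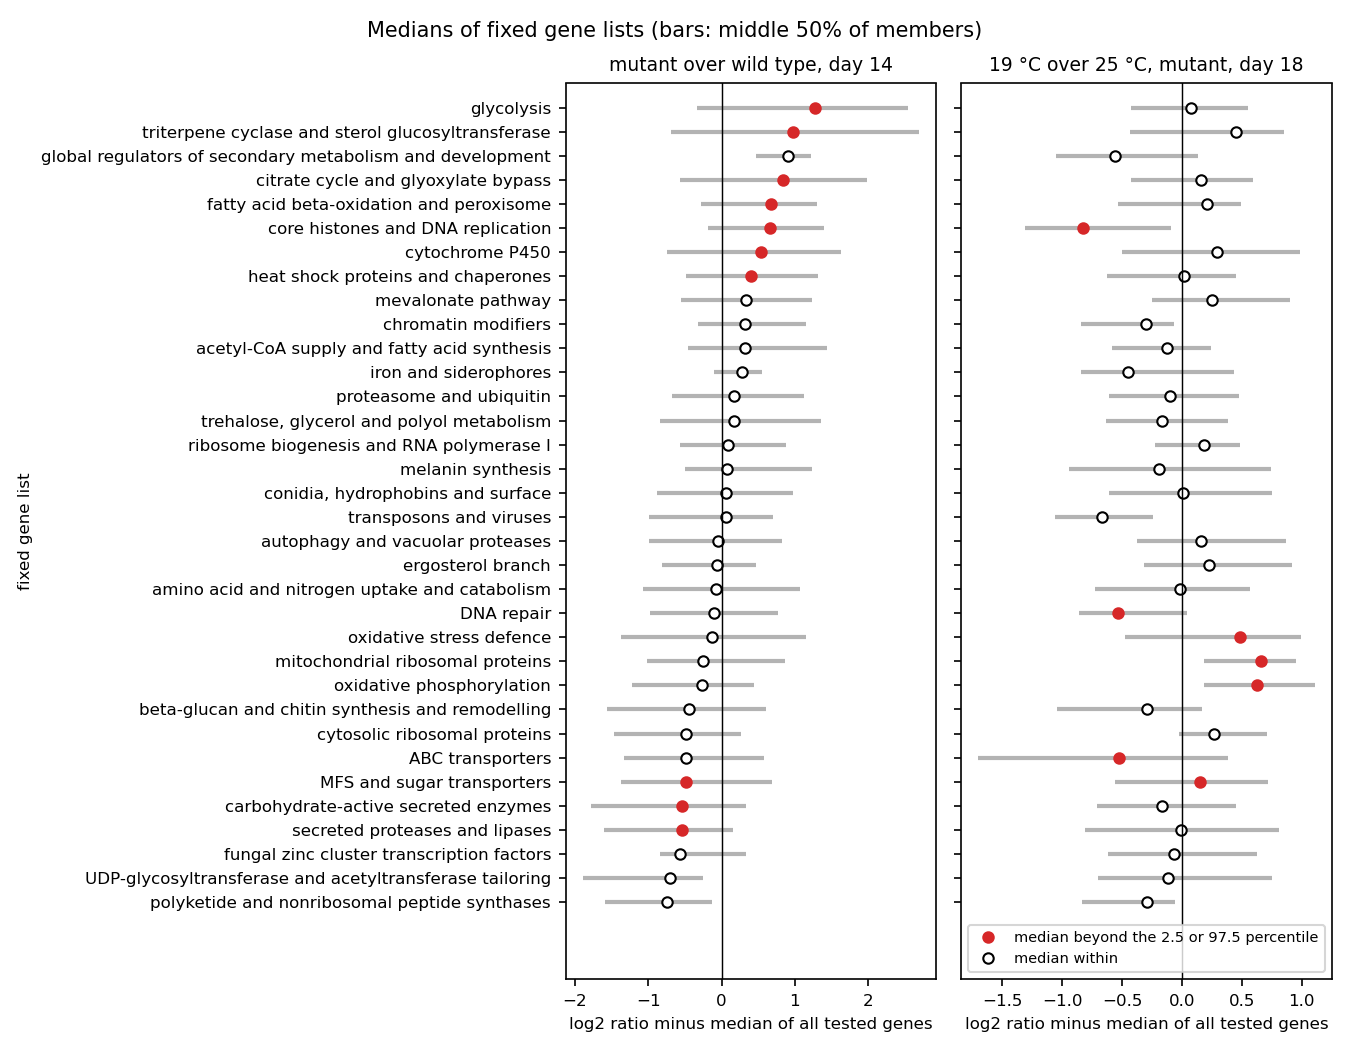
Medians of 34 fixed gene lists, drawn as log2 ratio minus the median of all tested genes, for the mutant against the wild type and for 19 °C against 25 °C. Bars span the middle 50% of members, and filled points have a median in the highest or lowest 2.5% of random lists; glycolysis lies highest in the strain comparison at 1.27, and histones and DNA replication lowest in the temperature comparison at -0.83.

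The mutant at day 18 was then compared between 19 °C and 25 °C, which addresses the effect of fermentation temperature. The enfumafungin synthase gene efuA (gene04134) hardly differed, at 1049 TPM at 19 °C and 887.3 TPM at 25 °C, while other cluster genes moved apart. The hydroxylase gene efuI (gene04131) was 3.58-fold higher at 19 °C, at 7402 and 2070 TPM, and the transporter model efuK (gene04128) 6.03-fold higher, at 191.4 and 31.7 TPM. The self-resistance gene efuJ (gene04130) went the other way and was 19.8-fold higher at 25 °C, at 90.1 and 1787 TPM. The other 10 cluster models lay within 2-fold on the log2 scale of TPM plus 1, among them efuB (gene04142) at 2.18 and 0.88 TPM. The lists of histones and DNA replication, of DNA repair and of ABC transporters were lower at 19 °C as groups, though the histones themselves went both ways.

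Of 9064 tested genes, 989 were at least 2-fold higher at 19 °C and 1942 lower, with a median log2 ratio of -0.21. Higher genes made up 33.7% of these calls as deposited and 37.9% after rescaling without the 20 highest genes. Rescaling by the median ratio, which by construction brings the median near 0, gave 45.4%. Of 36 lists, 5 had a median in the highest 2.5% of random lists and 3 in the lowest 2.5%. In the histone and DNA replication list 27 of 54 members were lower at 19 °C and 0 were higher, and the median lay at -0.83 relative to all genes. The mitotic cyclin-B gene (gene10851) stood at 16.9 TPM at 19 °C and 113.8 TPM at 25 °C, the helicase gene mcm7 (gene04329) at 28.9 and 160.5 TPM, and the large chain of ribonucleotide reductase (gene03460), which makes DNA precursors, at 26.9 and 158.1 TPM. Histone H4.1 (gene01010) had the list's largest ratio in the other direction, at 1618 TPM at 19 °C and 985.5 TPM at 25 °C, and histone H3 (gene01011) stood at 1538 and 963.0 TPM, whereas histone H2B (gene05347) stood at 1062 and 2845 TPM. In the DNA repair list 12 of 46 were lower and 1 higher. In the ABC transporter list 15 of 34 were lower and 0 higher, with the multidrug transporter atrF (gene09562) at 0.86 and 15.8 TPM. Mitochondrial ribosomal proteins had 7 of 50 members higher and 0 lower, with a median of 0.66 relative to all genes, and oxidative phosphorylation had 13 of 71 higher and 1 lower, with a median of 0.63. In the oxidative stress list 9 of 53 were higher and 6 lower. For sugar and other major facilitator transporters 25 of 163 were higher and 32 lower, and their median turned from -0.06 to 0.13 after rescaling by the median ratio, while their percentile of 97.8 became 94.3 with random lists not matched on expression.

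In the same pair of libraries, genes of long and of short proteins also stood apart. The 33 genes of proteins known to be very long had a median log2 ratio of -0.99, with 16 lower at 19 °C and 0 higher. The 55 genes of proteins known to be very short had a median of 0.53, with 12 higher and 2 lower. Within the oxidative phosphorylation list, the 78 kDa subunit of the NADH-ubiquinone oxidoreductase (gene08239) stood at 59.0 TPM at 19 °C and 181.1 TPM at 25 °C, against the list's direction.

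Among the named genes with the largest ratios, higher at 19 °C were endopolygalacturonase A (gene10082), at 150.2 and 0.18 TPM, the water and glycerol channel gene AQY3 (gene02800), at 195.7 and 1.37 TPM, the oxidoreductase gene BOA1 (gene10131), at 202.5 and 4.13 TPM, the P450 gene himC (gene09700), at 414.0 and 9.50 TPM, and the acetyltransferase gene aurG (gene06241), at 48.3 and 1.05 TPM. A second copy of hydroxymethylglutaryl-CoA synthase (gene06244) stood at 42.2 and 1.59 TPM and a second copy of the reductase (gene06242) at 26.4 and 2.72 TPM, whereas the main reductase copy (gene03104) stood at 39.7 and 155.3 TPM. Higher at 25 °C were a cyanovirin-N homolog (gene09524), at 22.6 TPM at 19 °C and 3152 TPM at 25 °C, pectin lyase A (gene05692), at 4.13 and 532.7 TPM, catalase B (gene05877), which breaks down hydrogen peroxide, at 4.53 and 556.9 TPM, and the calcium-responsive regulator gene CRZ1 (gene07846), at 13.8 and 446.6 TPM. A calcium-transporting ATPase gene (gene08022) stood at 1.90 and 118.8 TPM, an ammonium transporter gene (gene07015) at 3.77 and 195.5 TPM, a mannitol dehydrogenase gene (gene04859) at 0.71 and 61.6 TPM, the efflux pump gene notK' (gene09814) at 0.27 and 120.9 TPM, the P450 gene virE (gene07980) at 1.03 and 122.7 TPM, and a transporter gene of the ecdD type (gene01802) at 4.78 and 305.2 TPM. Heat shock genes had a median log2 ratio of -0.20, close to the -0.21 of all genes, with 3 of 57 higher at 19 °C and 13 lower. The small heat shock gene gene01826 stood at 2523 TPM at 19 °C and 273.6 TPM at 25 °C, and the Hsp12 gene (gene05573) at 34.0 and 418.0 TPM. Vacuolar transporter chaperone 2 (gene07808), ATP synthase subunit J (gene02679), a 19.3 kDa NADH-ubiquinone oxidoreductase subunit (gene04334), translation initiation factor 3 subunit B (gene07193) and the splicing protein gene DIB1 (gene07164) were listed at 0 at 25 °C and at 773.5, 257.3, 104.6, 78.2 and 60.1 TPM at 19 °C. Several of these genes are used by every cell, so they are only said to be listed at 0 and no ratio is given.

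The mutant at day 18 was last compared with the mutant at day 14, for which the temperature is not given in the sources used here, so time and temperature cannot be told apart. Both comparisons use the same day 14 library, and part of any agreement between them may come from it. At 25 °C, 5 of the 13 cluster models were lower than at day 14 and 0 were higher. At 19 °C, 4 were lower and 1, the transporter model efuK (gene04128), was higher, at 85.6 TPM at day 14 and 191.4 TPM at 19 °C. Rescaling by the median ratio moved the median log2 ratio of all genes by 0.32 at 25 °C and 0.50 at 19 °C. At 19 °C the calls for efuA, efuE and efuI, at -1.43, -1.17 and -1.10, therefore depended on the scaling, unlike that for efuJ at -3.34. At 25 °C efuJ, at 0.95, lay just within 2-fold, and its call depended on the scaling too. The efuA gene (gene04134) stood 3.19-fold above its 25 °C value and 2.70-fold above its 19 °C value at day 14. The siderophore transporter gene mirB (gene04089), which takes up iron chelates, had 443.1 TPM at day 14, 3.58 TPM at 19 °C and 8.82 TPM at 25 °C. A siderochrome transporter gene (gene05564) had 65.7 TPM at day 14, was listed at 0 at 19 °C and had 2.73 TPM at 25 °C, and the oxidoreductase gene OXR1 (gene01963) had 559.9, 8.62 and 9.12 TPM.

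At 25 °C, 1303 of 9236 genes were at least 2-fold higher at day 18 and 2249 lower, with a median log2 ratio of -0.30. At 19 °C, 727 of 9119 were higher and 2545 lower, with a median of -0.55. Higher genes made up 36.7% and 22.2% of these calls as deposited, and 33.4% and 22.5% after rescaling without the 20 highest genes. After rescaling by the median ratio, which by construction brings the median near 0, they made up 57.0% and 59.2%. Which direction prevailed thus depended on the scaling. Of 36 lists, 5 had a median in the highest 2.5% of random lists and 6 in the lowest 2.5% at 25 °C, and 1 and 5 at 19 °C. The iron and siderophore list, with 7 members, had 4 lower and 0 higher at 19 °C, at the 0.01 percentile, and 3 lower and 0 higher at 25 °C, at the 23.9 percentile. Ribosome biogenesis genes had a median in the highest 2.5% of random lists at both temperatures, with medians of 0.86 at 25 °C and 1.08 at 19 °C relative to all genes, and 18 of 66 and 15 of 66 members higher. At 25 °C the list of global regulators of secondary metabolism and development had a median of 1.02 relative to all genes, with 4 of 11 members higher and 1 lower, at the 98.8 percentile, against the 74.6 percentile at 19 °C. Nucleolar GTP-binding protein 2 (gene09526) had 13.2 TPM at day 14, 70.5 TPM at 19 °C and 58.0 TPM at 25 °C. At 19 °C, glycolysis had 8 of 20 members lower and 0 higher, with a percentile of 1.12 that became 14.4 with random lists not matched on expression, while at 25 °C it had 7 lower and 1 higher, at the 3.73 percentile. Fatty acid oxidation and peroxisomes had 20 of 46 members lower and 0 higher at 19 °C, at the 0.13 percentile, and 17 lower and 1 higher at 25 °C, at the 1.62 percentile. Trehalose, glycerol and polyol metabolism had 11 of 23 members lower and 1 higher at 19 °C, at the 0.08 percentile, and the 12.5 percentile at 25 °C. The citrate cycle list had 7 of 30 lower and 0 higher at 19 °C, where its percentile of 1.63 became 43.1 with random lists not matched on expression, and the 21.9 percentile at 25 °C. The cytochrome P450 list had 25 of 59 lower and 5 higher at 25 °C, at the 0.225 percentile, and 15 of 57 lower and 2 higher at 19 °C, at the 35.9 percentile. At 25 °C facilitator transporters had 55 of 172 lower and 18 higher, at the 0.29 percentile, mitochondrial ribosomal proteins 12 of 50 lower and 0 higher, at the 1.6 percentile, and oxidative phosphorylation 18 of 71 lower and 5 higher, at the 2.165 percentile. The latter 2 percentiles became 2.74 and 12.3 with random lists not matched on expression. Heat shock genes had 12 of 57 higher and 7 lower, at the 99.2 percentile, histones and DNA replication 9 of 55 higher and 7 lower, at the 97.8 percentile, and DNA repair 8 of 49 higher and 6 lower, at the 97.7 percentile, which became 94.7 without matching. The DNA repair median was 0.01 and turned to -0.06 after rescaling without the 20 highest genes. At 19 °C these 6 lists lay at the 47.7, 70.6, 53.5, 92.6, 3.67 and 69.6 percentiles. The list matched on source organism lay at the 0.05 percentile at 25 °C and the 24.9 percentile at 19 °C.

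Genes of long and short proteins also stood apart over time. At 25 °C the 33 long ones had a median log2 ratio of 0.30, with 5 higher and 0 lower, and the 55 short ones -0.89, with 2 higher and 23 lower. At 19 °C the medians were -0.74, with 0 higher and 8 lower, and -0.26, with 3 higher and 11 lower. Versatile peroxidase VPL1 (gene02133), a secreted oxidative enzyme, had 9.48 TPM at day 14, 429.8 TPM at 19 °C and 574.3 TPM at 25 °C. Flavohemoprotein (gene03962), which detoxifies nitric oxide, had 133.4, 5850 and 1055 TPM, and a short-chain dehydrogenase gene of the dmxR12 type (gene09461) had 9.38, 427.2 and 22.4 TPM. CRZ1 (gene07846) had 3.15 TPM at day 14, and an E3 ubiquitin ligase gene (gene09835) had 7.43 TPM at day 14 and 443.1 TPM at 25 °C.

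Strain and temperature ratios had a weak negative correlation across genes. Over 8828 genes tested in both, which are not independent replicates, Pearson's r was -0.06 and Spearman's rho -0.09, and these comparisons share no library. Of these genes, 397 were higher in both comparisons, against 395.1 for independent lists, and 216 were lower in both, against 236.8. In opposite directions, 921 were higher in the mutant and lower at 19 °C, against 772.7 for independent lists, and 184 were lower in the mutant and higher at 19 °C, against 121.1. Genes of proteins known to be very long had medians of 1.16 for strain and -0.99 for temperature. Those of very short ones had medians of 0.08 and 0.53. Whether the excess in opposite directions follows protein size was not tested.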

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

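The condition used here, and the narrower of the sets of genes it was applied to, were chosen after the values were seen. The genes below were looked at because, in the mutant, the difference between day 18 and day 14 went one way at 19 °C and the other way at 25 °C, each by at least 2-fold. The difference between the temperatures was not tested, since each group has 1 library, and both directions use the same day 14 library. Of 39 genes named for the temperature comparison by size or as triterpene genes, 13 met this condition, and of all 120 genes named for it, 24 did. Genes listed at 0 in any mutant library were not counted as meeting it, though they stayed in these totals. One is vacuolar transporter chaperone 2 (gene07808), at 171.4 TPM at day 14, 773.5 at 19 °C and 0 at 25 °C. Genes named for a large ratio between the temperatures meet the condition more easily, and the share over all genes was not computed.

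In 5 of these 13 genes the 19 °C library was the highest of the 3. The log2 ratio of 19 °C over 25 °C was 7.002 for endopolygalacturonase A (gene10082), 6.37 for the channel gene AQY3 (gene02800), 5.31 for the oxidoreductase gene BOA1 (gene10131), 5.30 for the P450 gene himC (gene09700) and 2.56 for the enfumafungin cluster transporter model efuK (gene04128). The day 14 values of these genes were 26.04, 5.54, 28.7, 118.7 and 85.6 TPM.

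In the other 8 the 25 °C library was the highest. The log2 ratio of 19 °C over 25 °C was -7.06 for the cyanovirin-N homolog (gene09524), -6.70 for pectin lyase A (gene05692), -6.66 for catalase B (gene05877), -6.58 for the efflux pump gene notK' (gene09814), -5.93 for the P450 gene virE (gene07980), -5.73 for the ecdD-type transporter gene (gene01802), -5.37 for the calcium-transporting ATPase gene (gene08022) and -5.36 for the ammonium transporter gene (gene07015). Their day 14 values were 191.8, 121.7, 47.9, 14.3, 6.57, 10.8, 8.64 and 36.3 TPM.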

How the results depend on the processing

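Counts without genes listed at 0, and the cytosolic ribosomal list without mitochondrial names, were chosen after seeing the data, and all other alternatives before. Of 64 alternative counts of higher or lower genes, 48 stayed within 1.5 times the reported one, those without genes listed at 0 among them. The correlation of strain with temperature ratios stayed within its bootstrap interval, -0.09 to -0.04, in all 6 alternatives. With a 4-fold threshold, which by construction calls fewer genes, 1677 genes were higher and 456 lower in the mutant, 234 and 478 at 19 °C against 25 °C, 407 and 432 at 25 °C against day 14, and 217 and 330 at 19 °C against day 14. Rescaling by the median ratio, which by construction moves all genes of a library together, gave 2281 higher and 2385 lower in the mutant, 1365 lower at 25 °C against day 14, and 1408 higher and 970 lower at 19 °C against day 14. A pseudocount of 5, which shrinks the ratios of low genes, gave 642 higher and 1280 lower at 19 °C against 25 °C and 1484 lower at 19 °C against day 14. Of 865 alternative list medians, 10 changed sign in lists with a median in the highest or lowest 2.5% of random lists. Changes of sign in other lists were not counted separately. A further 76 medians left the exact 95% interval of the reported median, of which 60 came from rescaling by the median ratio. In the strain comparison that rescaling gave -0.49 for facilitator transporters, -0.55 for carbohydrate-active enzymes and -0.47 for secreted proteases and lipases, and the 10 TPM filter gave -0.001 for carbohydrate-active enzymes. In the temperature comparison facilitator transporters turned to 0.13 under the median-ratio rescaling and 0.0109 without the 20 highest genes, and the list matched on source organism to 0.14 and 0.0403, and to 0.0135 with the 10 TPM filter. DNA repair at 25 °C against day 14 turned to -0.0621 without the 20 highest genes. For changes of sign under the filter and without the 20 highest genes the cause was not tested.

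With random lists not matched on expression, 128 of 144 list percentiles stayed on their side of the bounds, 7 came inside and 9 went outside, and the cause was not tested list by list. Those that came inside were heat shock (95.1) for strain, facilitator transporters (94.3) for temperature, oxidative phosphorylation (12.3), mitochondrial ribosomal proteins (2.74) and DNA repair (94.7) at 25 °C against day 14, and glycolysis (14.4) and the citrate cycle (43.1) at 19 °C against day 14. Those that went outside were cytosolic ribosomal proteins in all 4 comparisons (0.29, 99.1, 99.7 and 100), and, at 19 °C against day 14, oxidative phosphorylation (99.7), mitochondrial ribosomal proteins (98.2), heat shock (99.5), carbohydrate-active enzymes (1.13) and chromatin modifiers (1.49). The cytosolic list includes 38 genes named as mitochondrial. Without them its median left its exact interval in 1 of the strain and temperature comparisons and stayed inside in the other. No paired analysis was possible because each group has 1 library. Read depth is unknown, so which low values are at the limit of counting cannot be stated.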

Other observations

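The test of known long and short proteins between the day 14 libraries and the tests on genes listed at 0 over all libraries were written before their results were seen, though members of the protein classes were corrected afterwards; the tests by mass, those on genes listed at 0 in single libraries, those between the day 18 libraries and over time, and those on the run of neighbouring genes were chosen after results were seen.

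A stretch of 10 consecutive gene numbers, gene06239 to gene06248, bounded where the ratio dropped under 2-fold, was higher at 19 °C than at 25 °C, with a median log2 ratio of 3.26. It holds best hits to a geranylgeranyl pyrophosphate synthase (gene06243, 60.1 TPM at 19 °C and 2.47 TPM at 25 °C), the diterpene cyclase pimaradiene synthase pbcA (gene06248, 28.2 and 4.85 TPM), an acetyl-CoA synthetase (gene06239, 61.8 and 4.06 TPM), the acetyltransferase aurG (gene06241), and second copies of hydroxymethylglutaryl-CoA reductase (gene06242) and synthase (gene06244). The stretch was found by a scan of medians over 8 neighbouring tested genes, of which the 3 highest and 3 lowest were listed in the strain and in the temperature comparison. The scan's highest median for strain, 4.20 relative to all genes, fell on the enfumafungin genes gene04128 to gene04135. Among these gene04135, which has no database hit and sits beside efuA, stood at 362.4 TPM in the wild type and 4733 TPM in the mutant.

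For the 19 °C stretch the scan gave 4.06 relative to all genes, while 1000 random gene orders reached at most 3.26, which argues against a run met by chance among genes in random order. Ratios of neighbouring genes had a correlation of 0.14 in this comparison, which random orders do not keep. Whether such correlation could give a run of this size was not tested. Reads shared between copies stay open: of 4 genes in the scanned window with a name that no other gene has, the lowest log2 ratio was -0.0643, of a gene outside the stretch, and the median 2.43. Counted after this first form had failed to decide, and only described, 5 of the 10 stretch genes, or 50%, had such a name. Their log2 ratios were 1.96 to 4.59 with no copy named in the table, but the stretch was bounded at 2-fold, so a ratio under 1 could not occur in it, and copies under other names were not searched. A candidate explanation, as a hypothesis, is a diterpene gene cluster more expressed at the lower temperature; with 1 library per temperature, a difference between cultures stays open too.

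Known long and short proteins stood apart in all 4 comparisons, and of the 3 measures of size tried, long minus short over time was 1.19 (bootstrap interval over genes 0.75 to 1.58) at 25 °C and -0.48 (-0.78 to -0.14) at 19 °C by known proteins, 0.82 (0.03 to 1.22) and -0.62 (-1.04 to -0.14) by mass in the name, and 0.26 (-0.30 to 0.65) and -0.01 (-0.71 to 0.46) among ribosomal proteins. Between 19 °C and 25 °C, names stating 50 kDa or more (18 genes) and 25 kDa or less (25 genes) differed by -1.30 (-1.72 to -0.66), as a transcript length bias may give, while long and short ribosomal proteins differed by -0.39 (-1.02 to 0.03). Known long and short proteins differed by -1.52 (-1.92 to -1.22), a gap seen before its cause was asked. A few genes taking most of the TPM would move all others by 1 factor, which argues against that as the only cause. The 20 highest genes took 16.1% of the TPM at 19 °C and 14.1% at 25 °C. Between the strains the test written beforehand gave 1.07 (0.34 to 1.38), as a length bias in the other direction may give, but mass in the name gave 0.10 (-0.57 to 1.05) and ribosomal proteins 0.86 (-0.24 to 1.84), so by these measures it cannot be told apart from a strain difference. At 19 °C, the lower DNA replication, DNA repair and ABC transporter lists could follow in part from this trend. So could the higher oxidative phosphorylation and mitochondrial ribosomal lists there, the higher DNA replication list in the mutant, and lists over time. A response to temperature, strain or time stays open, untested. Of the lists named here for 19 °C, only oxidative phosphorylation has members whose names state a mass. Of the 25 genes with names stating 25 kDa or less, 12 are in the oxidative phosphorylation list. The known short proteins also include cytochrome c oxidase and ATP synthase subunits. For that list the trend is therefore no independent explanation.

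In the wild-type library 18 genes, and in the 25 °C library 10, were listed at 0 while the other 3 libraries had 10 TPM or more; the other libraries had 0 such genes. Too few reads would spare abundant genes. The share listed at 0 among genes at 50 TPM or more was 118.1% of that among genes at 10 to 20 TPM over all libraries, but this pools libraries that differ, so the bound of 25% set beforehand is applied to each. In the 25 °C library it was 358.1% (exact 95% interval 68.2 to 3532), which argues against too few reads there. In the wild type it was 50.01% (12.9 to 173.4). That interval lies above the share of under 10% predicted for too few reads but spans the bound of 25%, so by that bound it stays open. Reads given to a neighbouring copy stay possible for some of these genes. Of the 16 named ones, 12.5% had a gene of the same name within 5 gene numbers, against 0.499% of 5210 named genes at 10 TPM or more. That share lay under the 25% set beforehand for this cause but above 2 times the share of all named genes. It therefore does not decide, and it rests on 2 genes. Differences in sequence between the strains were not tested.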
